A study of Mus musculus with 18 samples.

How the data were processed

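The unit of every value used is raw fragments per gene, as in the deposited count tables: each holds whole-number counts for 41079 genes of GRCm39, 28108 of which had at least 1 fragment in any of 18 libraries. Library totals ran from 16053727 to 27207748 fragments, 0 columns could not be matched to a sample, and 0 pairs of libraries had identical counts. Per the submitters' processing notes, reads went through FastQC 0.11.9, fastp 0.23.2, HISAT2 2.1.0, featureCounts 2.0.3 of Subread and DESeq2. Per the file headers, featureCounts 1.6.2 counted fragments of read pairs over exons, by gene, from primary alignments and without regard to strand. The 2 versions differ, and which was used is not known. Because counting ignored strand, genes that overlap another gene, lie antisense to one or have near-identical copies may hold shared fragments, and their values are uncertain. Gene positions come from the count tables and are 1-based on GRCm39; the reference at hand was GRCm38 and was not used. Per the labels the material was total RNA of bone marrow cells selected for cKit, with libraries made by a service provider.

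Groups were 2 genotypes by 3 treatments with 3 libraries each. Comparisons, gene lists, main tests and other ways of testing were set before the data were examined; analyses without WT replicate 2, a random-effect fit of the genotype contrast and the tests of explanations were added afterwards. Compounds were compared within the 9 libraries of a genotype, and genotypes and differences between their responses in a fit of all 18. Genes with enough counts by filterByExpr were kept (14704 in AE9a, 15046 in WT and 15809 in all libraries), scaled by TMM and tested by edgeR quasi-likelihood F tests with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 0.103 in AE9a, 0.329 in WT and 0.243 in all libraries. Also run were DESeq2, limma-voom, other scalings, other filters, replicate numbers as blocks, other sets of libraries and leaving out each library in turn. Under RLE and upper-quartile scaling no median log2 change moved by more than 0.04. Standard errors are those of the fitted log2 change. Levels are CPM with SD over 3 libraries.

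Whether replicate numbers pair samples was read from deviations of genes from their group means. Same-number correlations were 0.62, 0.77 and 0.62 between WT DMSO and C16, 0.63, 0.84 and 0.63 between WT DMSO and RE, and 0.53, 0.72 and 0.62 between WT C16 and RE. WT replicate 2 lay far from replicates 1 and 3 under each treatment. As deviations are from group means, that alone can give replicates 1 and 3 such correlations. By root mean square log2 difference, WT DMSO 1 and WT DMSO 3 each lay 0.52 from WT C16 1 and 0.57 from WT C16 3. Numbers thus set replicate 2 apart, but pairing of WT replicates 1 and 3 by number is not shown. Same-number correlations were 0.34, 0.25 and 0.31 between AE9a DMSO and RE, but 0.06, 0.25 and 0.14 between AE9a DMSO and C16 and 0.11, 0.11 and 0.1 between AE9a C16 and RE, where pairing is not shown. Blocked values stand beside some of the results whose call or count they change. With blocks the coefficient of variation was 0.137 in WT and 0.082 in AE9a.

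Gene lists were 17 lists of programs and 10 lists of cell type markers, written from general knowledge, 25 of which had at least 5 tested genes in AE9a cells. List tests were camera with a preset inter-gene correlation of 0.01, camera with an estimated correlation, and fry. Genes named one by one were the 10 largest rises and falls of a comparison (5 for direct compound contrasts and genotype differences). These had adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap of libraries. Up to 4 genes per list and 10 genes set in advance were added. The text prints only some of them, and not always those from the top. For genotype differences no overlap refers to changes of each library from its DMSO group mean. A group with 0 fragments is given as "at least" a fold, against 3 fragments over the group, and groups with 1 to 3 fragments as a ratio with an interval; these cover counting error only. The effect of shared controls was measured by 20 simulations without responses. Those for the genotype difference held no genotype difference either.

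A self-test drew counts like those of each comparison and changed 100 genes by 2-fold and 100 by 4-fold. The changed genes were drawn only from those over a minimum mean level, and no other gene changed between the groups compared. Recovery of genes at lower levels was not measured. Recovered were 87% and 96% for C16 and 89% and 98% for RE in AE9a cells, 91% and 99% for C16 against RE in them, and 63% and 94% for the genotypes under DMSO. In WT cells 27% and 80% were recovered for C16, 27% and 88% for RE and 26% and 81% for C16 against RE, or 75% and 98%, 80% and 100%, and 79% and 100% with blocks. For the genotype difference in response 40% and 77% were recovered for C16 and 45% and 75% for RE. False calls made up 2.1% to 7.4% of calls, and 0 of 20 unchanged gene sets were called. Work was done with R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.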

Results

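Transcripts were counted in cKit-positive mouse bone marrow cells, either wild type (WT) or carrying AE9a, a splice form of the AML1-ETO fusion of RUNX1 and RUNX1T1. Cells of each genotype had received DMSO, C16 or RE, with 3 libraries per group and 18 in all. The study describes inhibition of WDR5 and of MLL1, but the labels do not say which of C16 and RE acts on which, at what dose or for how long. Runx1t1 (chromosome 4, 13742628 to 13895056, GRCm39) parted the genotypes: it stood at 40 ± 6.26 CPM (counts scaled to library size, mean ± SD of 3 libraries) in AE9a DMSO cells and at 0.11 CPM in WT DMSO cells, and reached at most 0.4 CPM in any of the 9 WT libraries. Whether the transgene carries the human or the mouse sequence is not known and reads were not at hand, so how much of its transcript this level counts is open. Runx1 counts in AE9a cells may likewise include fragments of the fusion transcript. Nanog (chromosome 6, 122684448 to 122691592), which the study names, had 0 fragments in all 18 libraries, under a detection floor of 3 fragments that equals 0.11 to 0.187 CPM. Wdr5 (chromosome 2, 27405159 to 27426547) stood at 138.2 CPM in AE9a DMSO cells and did not part the genotypes (log2 −0.13, adjusted p = 0.44). Log2 fold changes are given with their sign, ± standard error and with n = 3 libraries per group, and p values are adjusted over all tested genes unless a list is named. The labels do not say whether replicates came from separate animals, so the p values may measure only the spread between these samples. Counts came as a separate table for each genotype, and library batch may follow genotype. Differences between AE9a and WT cells therefore cannot be told apart from differences of batch or preparation.

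**Figure D1:**
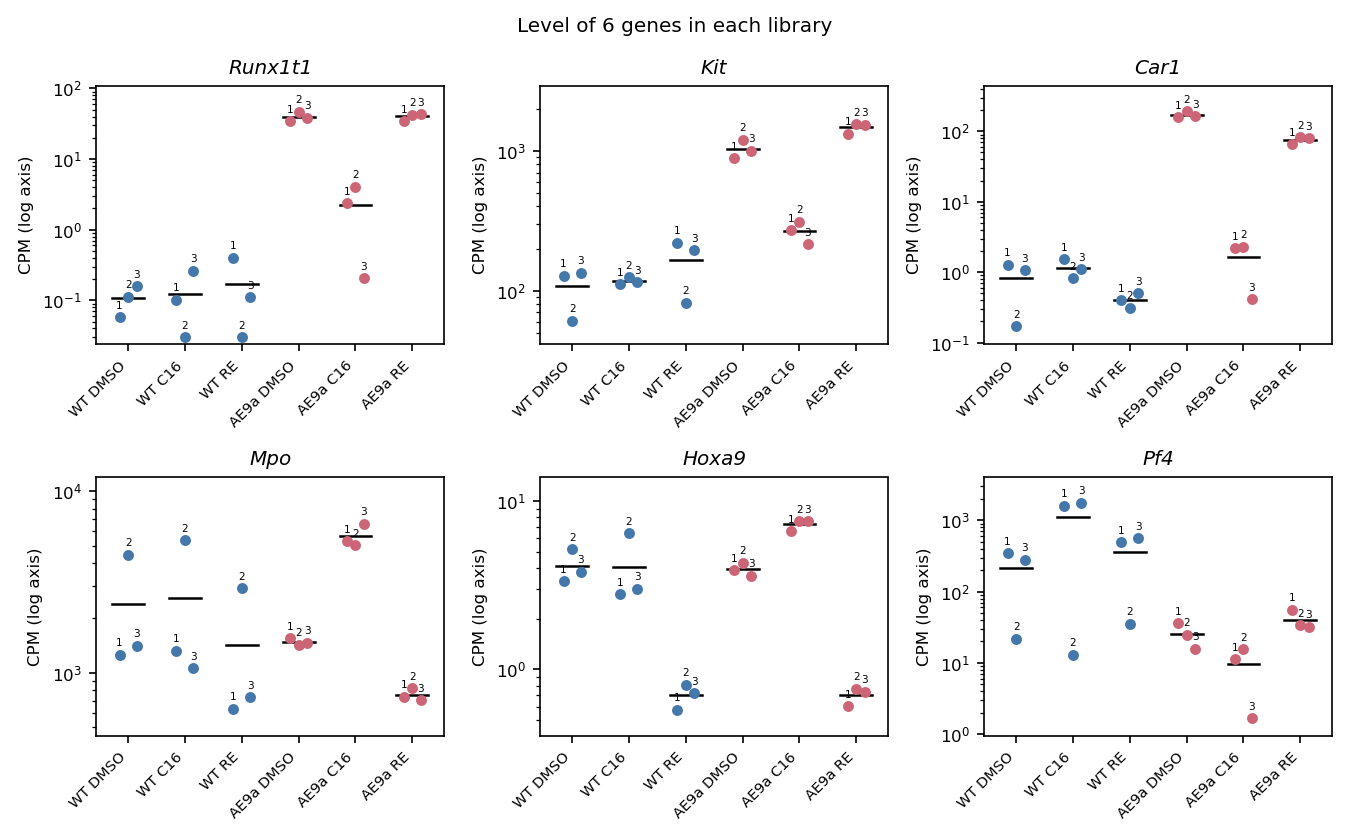
Levels of Runx1t1, Kit, Car1, Mpo, Hoxa9 and Pf4 in each of the 18 libraries, in CPM on a log axis, with points numbered by replicate, a black bar at the group mean and values under 0.03 CPM drawn at 0.03. Among AE9a libraries Runx1t1, Kit and Car1 are lowest under C16, Hoxa9 is low in RE libraries of each genotype, and Pf4 is low in WT replicate 2.

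Some erythroid and mast cell genes, Car1, Ermap, Tpsab1 and Mcpt4 among them, stood far higher in AE9a than in WT cells under DMSO. Car1 (chromosome 3, 14831274 to 14873425), a carbonic anhydrase gene of red cell precursors, stood at 171.3 CPM against 0.832 CPM (log2 7.70 ± 0.53, adjusted p = 5.5e-07), and Ermap, which encodes an erythroid membrane protein, at 45.6 CPM against 0.257 CPM (log2 7.45 ± 0.55). The mast cell protease genes Tpsab1 and Mcpt4 stood at 366.7 and 459.4 CPM in AE9a cells against 0.312 and 0.272 CPM in WT cells. Kit (chromosome 5, 75735647 to 75817382) was higher by 3.28 ± 0.33 (adjusted p = 1e-05), with 1031.0 ± 162.3 CPM against 107.8 ± 40.8 CPM. Genes with 0 fragments in WT DMSO cells included Kcnc4 (at least 421-fold higher in AE9a cells), Reln (at least 230-fold) and Wt1 (at least 184-fold).

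Of 22 erythroid genes tested, 12 were higher and 2 lower in AE9a cells (13 and 2 when adjusted over the list alone), with a median log2 of 1.54 (camera adjusted p = 4.4e-10, and adjusted p = 0.76 with an estimated correlation). Of 28 interferon response genes, 17 were higher and 0 lower (23 and 0 over the list alone). The interferon median was 2.12 (camera adjusted p = 7.1e-08, and adjusted p = 0.76 with an estimated correlation). Oas3 was higher by 3.27 ± 0.60 (196.4 against 20.7 CPM) and Irf7 by 3.08 ± 0.66 (100.6 against 12.1 CPM). The interferon list also varied among AE9a libraries, its median against WT DMSO cells being 2.31, 1.94 and 0.85 in AE9a DMSO replicates 1, 2 and 3. Of 22 mast cell, basophil and eosinophil genes, 10 were higher and 4 lower (10 and 4 over the list alone). The mast cell median was 0.99 (camera adjusted p = 0.036, and adjusted p = 0.76 with an estimated correlation). The lower count of that list was 2 without WT DMSO 3 and 2 without AE9a DMSO 2, and its camera adjusted p was 0.1, 0.093 and 0.091 without WT DMSO 1, WT DMSO 2 and AE9a DMSO 1. Of 36 cell cycle genes, 0 were higher and 0 lower by edgeR, and 20 were higher and 1 lower without WT replicate 2.

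Genes lower in AE9a cells lay in the B lineage, p53, megakaryocyte and HSC lists, among others. Of 15 B lineage genes, 7 were lower (11 over the list alone). The B lineage median was −1.43 (camera adjusted p = 0.002, and adjusted p = 0.76 with an estimated correlation). Ighm was lower by −1.42 ± 0.27. The B lineage count was 4, 12, 2 and 2 without WT DMSO 1, AE9a DMSO 1, AE9a DMSO 2 and AE9a DMSO 3 in turn and 12 without WT replicate 2. Of 25 p53 target genes, 8 were lower (11 over the list alone). The p53 median was −0.85 (camera adjusted p = 0.0018, and adjusted p = 0.76 with an estimated correlation). The p53 count was 4, 13, 5, 5, 4 and 5 without WT DMSO 1, 2 and 3 and AE9a DMSO 1, 2 and 3 in turn and 22 without WT replicate 2. Of 16 megakaryocyte and platelet genes, 3 were lower (6 over the list alone): Itgb3 by −2.72 ± 0.82, Vwf by −3.28 ± 1.15 and Gp6 by −5.36 ± 1.89. The megakaryocyte median was −3.17 (camera adjusted p = 0.044, and adjusted p = 0.76 with an estimated correlation). The megakaryocyte count was 0, 8, 0, 0, 0 and 0 without WT DMSO 1, 2 and 3 and AE9a DMSO 1, 2 and 3 in turn and 15 without WT replicate 2. The camera adjusted p of that list was 0.16, 0.11, 0.052 and 0.078 without WT DMSO 1, WT DMSO 3, AE9a DMSO 1 and AE9a DMSO 3. Of 28 HSC and stemness genes, 9 were lower and 2 higher (11 and 2 over the list alone). The HSC median was −0.82 (camera adjusted p = 0.096, and adjusted p = 0.76 with an estimated correlation). Of the HSC genes 5 were lower without WT DMSO 1, 12 lower and 1 higher without WT DMSO 2 (camera adjusted p = 0.004), and 17 lower and 4 higher without WT replicate 2. Single genes lower in AE9a cells included Ctsk (−4.21 ± 0.58, 1.25 against 23.9 CPM), Cdh17 (−3.72 ± 0.44), Cxcr2 (−2.81 ± 0.34, 20.5 against 146.0 CPM) and Pecam1 (−1.69 ± 0.16). Larger falls included Arg1 (−6.24, adjusted p = 0.017) and Cd226 (−4.32, adjusted p = 0.016). The call of Arg1 was lost without WT DMSO 2 (−4.00, adjusted p = 0.097) or any AE9a DMSO library, and that of Cd226 without AE9a DMSO 2 or 3. Meis1 was lower by −1.69 ± 0.57 (adjusted p = 0.042), a call that was lost without WT DMSO 1 (adjusted p = 0.13), WT DMSO 3 (0.11), AE9a DMSO 1 (0.1), AE9a DMSO 2 (0.1) and AE9a DMSO 3 (0.11). Hoxa9 showed −0.04 (adjusted p = 0.93).

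In all, 2047 genes were higher and 2178 lower in AE9a DMSO than in WT DMSO cells of 15809 tested by edgeR, 962 and 1060 of them by at least 2-fold. The 3 AE9a libraries did not overlap the 3 WT libraries for 7559 genes (47.8%), against 10% by chance. WT replicate 2 stood apart from the other WT samples in megakaryocyte and other genes, and without its 3 libraries the count was 8172, with 4003 higher and 4169 lower. DESeq2 gave 2676 higher and 2260 lower.

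C16 lowered 19 of 22 erythroid genes and 19 of 22 mast cell, basophil and eosinophil genes in AE9a cells, and with them Runx1t1. Car1 fell from 171.3 ± 19.2 to 1.63 ± 1.06 CPM (log2 −6.63 ± 0.31, adjusted p = 1.4e-06), Ermap by −6.95 ± 0.33 (0.341 against 45.6 CPM), and Klf1, the erythroid transcription factor gene, by −4.01 ± 0.26 (adjusted p = 2.6e-06). Runx1t1 fell by −4.07 ± 0.46 (adjusted p = 4.4e-05), to 2.35, 4.06 and 0.205 CPM in AE9a C16 replicates 1, 2 and 3, the last within the range of WT libraries. WT C16 replicate 2 lay nearer to the AE9a C16 libraries than to its own group: the root mean square log2 difference was 0.50, 0.52 and 0.50 from AE9a C16 replicates 1, 2 and 3, and 0.90 and 0.95 from WT C16 replicates 1 and 3. It was 0.49 from WT DMSO replicate 2. AE9a C16 replicate 3 also stood apart from its group, at 0.46 and 0.49 from AE9a C16 replicates 1 and 2, which lay 0.15 from each other. What the text says of C16 in each genotype takes the labels of these libraries as given. Kit fell by −1.92 ± 0.16 (265.5 ± 48.7 against 1031.0 ± 162.3 CPM) and Runx1 (chromosome 16, 92398354 to 92622962) by −1.29 ± 0.10 (138.3 against 347.1 CPM). How much of the Runx1 fall belongs to the fusion transcript is open. Mpo (chromosome 11, 87684610 to 87695238), the myeloperoxidase gene, rose by 1.97 ± 0.10 to 5655.3 ± 837.4 CPM.

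Of 22 erythroid genes, 19 fell and 1, Tfrc, rose in AE9a cells under C16 (19 and 1 over the list alone). The erythroid median was −3.42 (camera adjusted p = 6.9e-11, and adjusted p = 0.4 with an estimated correlation). Rhag had 2 fragments in C16 and 314 in DMSO libraries, a ratio of 153 (95% counting interval 42.1 to 1270). Of 22 mast cell, basophil and eosinophil genes, 19 fell and 0 rose (19 over the list alone). The mast cell median was −3.04 (camera adjusted p = 0.00092, and adjusted p = 0.64 with an estimated correlation). Hdc, the histidine decarboxylase gene, fell by −4.08 ± 0.42 from 1508.6 to 86.8 CPM. Of 15 megakaryocyte and platelet genes, 12 fell (14 over the list alone), Gp1ba by −2.48 ± 0.23, with a list median of −2.0 (camera adjusted p = 0.0095, and adjusted p = 0.68 with an estimated correlation). Myeloid genes divided. Of 13 primary granule genes, 12 rose (13 over the list alone), among them Prtn3 (1.68 ± 0.07, 1339.3 against 428.2 CPM) and Ctsg (1.69 ± 0.08). The primary granule median was 1.11 (camera adjusted p = 8.3e-09, and adjusted p = 0.4 with an estimated correlation). Of 17 maturing neutrophil genes, 13 fell (13 over the list alone), among them Cd177 (−2.96 ± 0.11) and Ngp (−2.32 ± 0.16, 140.7 against 717.0 CPM). The maturing neutrophil median was −1.46 (camera adjusted p = 2.2e-05, and adjusted p = 0.59 with an estimated correlation).

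All 36 cell cycle genes rose in AE9a C16 cells (36 over the list alone). The cell cycle median was 0.77 (camera adjusted p = 2.4e-17, and adjusted p = 0.4 with an estimated correlation). Cdc20 rose by 1.02 ± 0.06 from 78.3 to 154.6 CPM. All 25 ribosome biogenesis genes rose as well (25 over the list alone), with a median of 0.64 (camera adjusted p = 2.7e-15, and adjusted p = 0.4 with an estimated correlation). Npm1 rose by 1.22 ± 0.06 to 2227.1 CPM. Of 23 inflammatory and NF-kB genes, 14 fell and 2 rose (14 and 2 over the list alone), Tnfaip3 by −1.44 ± 0.13, with a list median of −0.46 (camera adjusted p = 0.026, and adjusted p = 0.4 with an estimated correlation). Of 15 HOXA-MEIS1 genes, 9 rose and 2 fell (9 and 2 over the list alone). The HOXA-MEIS1 median was 0.61 (camera adjusted p = 0.15, and adjusted p = 0.4 with an estimated correlation). Hoxa9 rose by 0.92 ± 0.13 from 3.93 to 7.27 CPM and Pbx3 fell by −1.46 ± 0.12. Of 21 WDR5 and MLL complex genes, 11 rose and 5 fell (11 and 5 over the list alone): Dpy30 rose by 0.97 ± 0.07 and Wdr5 by 0.33 ± 0.04, and Kmt2a showed −0.05 ± 0.04 (adjusted p = 0.29). The list of AML1-ETO reported genes was, like the others, written from general knowledge. Of its 20 genes 7 rose and 9 fell (7 and 9 over the list alone), with a median of 0.04. Jup fell by −2.37 ± 0.13 and Cebpa rose by 1.11 ± 0.08.

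In total 4870 genes rose and 4875 fell of 14704 tested by edgeR, and of the changes of at least 2-fold 424 were rises and 2172 were falls. Libraries of the groups did not overlap for 10393 genes (70.7%), against 10% by chance.

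**Figure D2:**
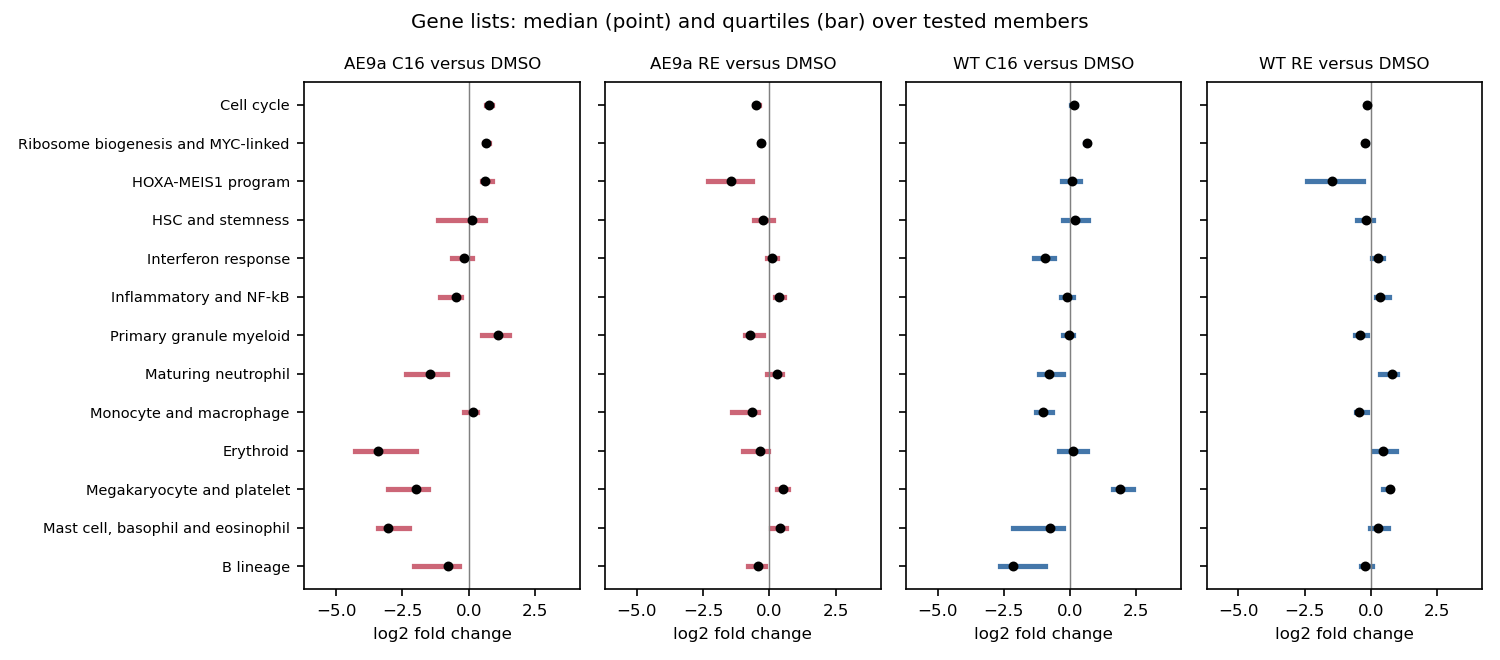
Median log2 fold change (point) and quartiles (bar) over the tested genes of 13 lists, for C16 and RE against DMSO in WT and AE9a cells, 3 libraries per group. In AE9a cells the cell cycle, ribosome biogenesis and primary granule lists lie above 0 under C16 and below 0 under RE, and the HOXA-MEIS1 list lies below 0 under RE in each genotype.

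RE lowered 9 of 15 HOXA-MEIS1 genes, 35 of 36 cell cycle genes and 10 of 13 primary granule genes in AE9a cells. Hoxa9 (chromosome 6, 52200077 to 52203169) fell by −2.43 ± 0.16 (adjusted p = 0.00017), from 3.93 ± 0.345 to 0.702 ± 0.0865 CPM, and Hoxa7 (chromosome 6, 52191471 to 52198757) by −3.35 ± 0.26, from 5.65 to 0.546 CPM. Mef2c fell by −1.16 ± 0.11 (20.7 against 47.6 CPM), Flt3 by −1.43 ± 0.17 and Adgrl4, an adhesion receptor gene, by −3.31 ± 0.44. Genes that rose included Cpeb1 (2.77 ± 0.39, 12.1 against 1.81 CPM), Amigo2 (2.14 ± 0.22) and Clec10a (1.96 ± 0.31, 77.1 against 20.4 CPM). Runx1t1 showed 0.05 ± 0.35 (adjusted p = 0.94), Wdr5 −0.12 (adjusted p = 0.07) and Kmt2a −0.04 (adjusted p = 0.54).

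Of 15 HOXA-MEIS1 genes, 9 fell and 0 rose (11 and 0 over the list alone). The HOXA-MEIS1 median was −1.43 (camera adjusted p = 7.4e-12, and adjusted p = 0.008 with an estimated correlation). With replicate numbers as blocks, which pair AE9a DMSO and RE libraries, adjusted p = 0.1 with an estimated correlation for that list. Of 36 cell cycle genes, 35 fell (36 over the list alone), Cdc6 by −0.66 ± 0.04 and Top2a by −0.60 ± 0.06. The cell cycle median was −0.50 (camera adjusted p = 1.2e-31, and adjusted p = 0.24 with an estimated correlation). Of 25 ribosome biogenesis genes, 24 fell (24 over the list alone). The ribosome biogenesis median was −0.32 (camera adjusted p = 1.1e-12, and adjusted p = 0.24 with an estimated correlation). Of 13 primary granule genes, 10 fell (11 over the list alone). The primary granule median was −0.73 (camera adjusted p = 1.2e-12, and adjusted p = 0.14 with an estimated correlation). Mpo fell by −0.93 ± 0.10 (754.1 against 1482.0 CPM) and Prtn3 by −1.0 ± 0.07 (207.8 against 428.2 CPM). Of 19 monocyte and macrophage genes, 8 fell (9 over the list alone), F13a1 by −1.41 ± 0.12. The monocyte median was −0.66 (camera adjusted p = 2.8e-06, and adjusted p = 0.24 with an estimated correlation). Of 23 inflammatory and NF-kB genes, 6 rose and 1 fell (7 and 1 over the list alone). The NF-kB median was 0.35 (camera adjusted p = 0.0016, and adjusted p = 0.24 with an estimated correlation). The NF-kB genes that rose numbered 1 without AE9a DMSO 1 and 3 without AE9a RE 2. Of 22 erythroid genes, 8 fell (9 over the list alone). The erythroid median was −0.35 (camera adjusted p = 0.00097, and adjusted p = 0.66 with an estimated correlation). The erythroid count was 5, 5 and 5 without AE9a DMSO 1, AE9a DMSO 3 and AE9a RE 2 in turn. Car1 fell by −1.13 ± 0.21, to 75.8 CPM. Kit rose by 0.56 ± 0.15 (adjusted p = 0.023), a call lost without AE9a DMSO 1 (adjusted p = 0.087), AE9a DMSO 3 (0.072), AE9a RE 2 (0.08) and AE9a RE 3 (0.075).

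In AE9a cells under RE, 1797 genes rose and 2464 fell of 14704 tested by edgeR, 252 and 192 of them by at least 2-fold. Libraries of the groups did not overlap for 7384 genes (50.2%), against 10% by chance. The count of 4261 was 2351, 2458 and 2790 without AE9a DMSO 1, AE9a RE 2 and AE9a RE 3, and 500 when all 18 libraries shared 1 fit. The excess of falls depends on the setting: 337 of those 500 rose and 163 fell, and upper-quartile scaling gave 2166 rises and 2075 falls.

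**Figure D3:**
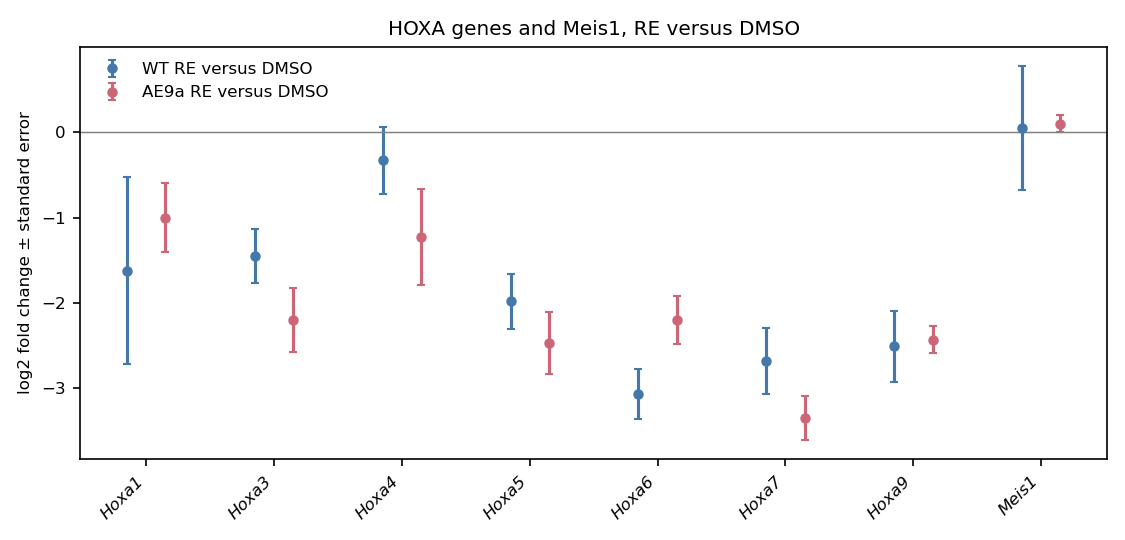
Log2 fold change of RE against DMSO with standard error (bars) for each tested HOXA gene of the HOXA-MEIS1 list and Meis1 in WT and AE9a cells, 3 libraries per group. The HOXA points lie below 0 in each genotype, and Meis1 lies close to 0.

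Set against RE directly, C16 left AE9a cells with more Hoxa9, Hoxa7 and Mpo transcripts and with fewer Car1 and Hdc transcripts. Hoxa9 was higher by 3.34 ± 0.16 (7.27 against 0.702 CPM, adjusted p = 2e-07), Hoxa7 by 3.91 ± 0.25, Mpo by 2.90 ± 0.10 and Adgrl4 by 4.95 ± 0.42. Ppbp, a platelet chemokine gene, was lower by −6.17 ± 0.82, Car1 by −5.50 ± 0.31, Hdc by −5.00 ± 0.44 (86.8 against 2758.5 CPM), Runx1t1 by −4.12 ± 0.46 and Kit by −2.48 ± 0.16. Wdr5 was higher by 0.46 ± 0.04 (adjusted p = 1.2e-05).

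All 36 cell cycle genes were higher under C16 than under RE (36 over the list alone). The cell cycle median was 1.30 (camera adjusted p = 1.4e-25, and adjusted p = 0.27 with an estimated correlation). All 25 ribosome biogenesis genes were higher, with a median of 0.97 (camera adjusted p = 1.6e-17, and adjusted p = 0.27 with an estimated correlation). All 13 primary granule genes were higher. The primary granule median was 1.80 (camera adjusted p = 3.7e-11, and adjusted p = 0.16 with an estimated correlation). Of the HOXA-MEIS1 list, 12 of 15 genes were higher and 2 lower, with a median of 2.65 (camera adjusted p = 0.00082, and adjusted p = 0.16 with an estimated correlation). Lower under C16 were 18 of 22 erythroid genes, with 1 higher and a median of −2.92 (camera adjusted p = 8.2e-05, and adjusted p = 0.68 with an estimated correlation), and 14 of 15 megakaryocyte genes, with a median of −2.60 (camera adjusted p = 0.011, and adjusted p = 0.78 with an estimated correlation). Of 22 mast cell, basophil and eosinophil genes, 19 were lower and 1 higher, with a median of −3.40 (camera adjusted p = 0.0055, and adjusted p = 0.78 with an estimated correlation). The counts of these lists were the same when adjusted over each list alone. By edgeR 5511 genes were higher and 5465 lower of 14704 tested, 1363 and 2683 of them by at least 2-fold, and libraries did not overlap for 11429 genes (77.7%), against 10% by chance.

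The C16 and RE responses of AE9a cells ran in opposite directions over 14704 genes, with a correlation of −0.37 (Spearman −0.54). The groups share their DMSO libraries, and 20 simulations without any response gave a mean correlation of 0.49 (Spearman 0.44). The covariance was −0.179 against 0.025 in the simulations, a difference of −0.204. Of genes that rose with each compound 76 were shared against 595 if the sets were independent, and of genes that fell 188 were shared against 817. In WT cells the correlation was 0.18 against 0.49 in the simulations, the covariance differed from theirs by 0.015, and 0 genes were shared where 0.0859 would be if independent. With 3 DMSO libraries per genotype the controls could not be split between the contrasts. Sharing them raised the covariance in the simulations, which argues against sharing as the source of the opposite directions in AE9a cells. In WT cells part of the excess of 0.015 may come from sharing.

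In the fit of all 18 libraries, 1347 genes higher in AE9a than in WT cells fell with C16 against 440 if the sets were independent, Car1, Kit and Runx1t1 among them. Over all genes the correlation between the C16 change in AE9a cells and the genotype difference was −0.46 (Spearman −0.23). Simulations without responses and without a genotype difference gave −0.49 (Spearman −0.45) from the shared DMSO libraries alone. As these data hold a genotype difference, that value is not what chance would give here. The correlation therefore cannot show whether there is opposition beyond sharing. The covariance was −0.661 against −0.078 in the simulations. Of genes lower in AE9a cells, 601 rose with C16 against 528. For RE the correlation was 0.08 against −0.49 in simulations of the same kind. Of genes lower in AE9a cells 36 rose against 46.4, and of genes higher in AE9a cells 9 fell against 21.1. Part of the opposite changes may come from the shared AE9a DMSO libraries.

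In WT cells C16 lowered the eosinophil genes Epx and Prg2 and 7 of 15 B lineage genes. Epx (chromosome 11, 87754824 to 87766362), the eosinophil peroxidase gene, fell by −4.55 ± 0.42 (adjusted p = 0.017), from 207.2 ± 114.6 to 8.4 ± 2.6 CPM, and Prg2 by −3.34 ± 0.36 (24.6 against 261.9 CPM). The B lineage genes Pax5 and Ebf1 fell by −2.77 ± 0.44 and −3.46 ± 0.40, and Cxcr2 by −1.25 ± 0.17 (58.6 against 146.0 CPM). Slc26a3 rose by 2.89 ± 0.42, from 0.974 to 7.01 CPM, and Ass1, the argininosuccinate synthase gene, by 1.55 ± 0.15, from 30.8 ± 4.95 to 86.3 ± 2.56 CPM. All of these calls were lost without WT DMSO 1, WT C16 1 or WT C16 3, when 0 genes passed (adjusted p for Epx 0.098, 0.09 and 0.085). All but those of Epx and Prg2 were lost without WT DMSO 3, when 2 genes passed (adjusted p for Ass1 0.099), and that of Slc26a3 without WT DMSO 2 (0.052). These fits did not use replicate numbers as blocks. Blocks, which also take up the distance of WT replicate 2, lowered the coefficient of variation from 0.329 to 0.137. Whether the calls would also be lost in a blocked fit was not examined. Hoxa9 showed 0.07 ± 0.38 (adjusted p = 0.93), Kit 0.19 (adjusted p = 0.8) and Wdr5 −0.08 (adjusted p = 0.8).

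Of 15 B lineage genes, 7 fell in WT cells under C16 (10 over the list alone). The B lineage median was −2.16 (camera adjusted p = 2.7e-10, and adjusted p = 0.58 with an estimated correlation). Of 27 interferon response genes, 4 fell (10 over the list alone and 19 with replicate blocks), Zbp1 by −1.72 ± 0.20. The interferon median was −0.95 (camera adjusted p = 1.3e-08, and adjusted p = 0.58 with an estimated correlation). These B lineage and interferon counts were 0 without WT DMSO 1, 0 without WT DMSO 3, 0 without WT C16 1 and 0 without WT C16 3 (adjusted p for Zbp1 0.1, 0.099, 0.09 and 0.085), and 12 and 23 without WT replicate 2. Of 18 mast cell, basophil and eosinophil genes, 3 fell (5 over the list alone and 10 with replicate blocks). The mast cell median was −0.75 (camera adjusted p = 2.8e-05, and adjusted p = 0.58 with an estimated correlation). The mast cell count was 0 without WT DMSO 1, 0 without WT C16 1, 0 without WT C16 3 and 10 without WT replicate 2, and the camera adjusted p was 0.062 without WT C16 2. Of 19 monocyte and macrophage genes, 3 fell (8 over the list alone and 12 with replicate blocks). The monocyte median was −1.03 (camera adjusted p = 4.8e-06, and adjusted p = 0.59 with an estimated correlation). The monocyte count was 0, 1, 0, 0, 6 and 0 without WT DMSO 1, 2 and 3 and WT C16 1, 2 and 3 in turn and 14 without WT replicate 2. Of 25 ribosome biogenesis genes, 0 rose at the all-gene threshold and 24 over the list alone. The ribosome biogenesis median was 0.64 (camera adjusted p = 6.3e-15, and adjusted p = 0.58 with an estimated correlation). The ribosome biogenesis genes that rose numbered 21 with replicate blocks and 7 without WT C16 2. Dkc1 showed 0.68 ± 0.15 (adjusted p = 0.055, and 0.021 with blocks). Of 16 megakaryocyte genes, 0 changed (camera adjusted p = 0.051, median 1.88), 9 rose with replicate blocks (camera adjusted p = 0.00038) and 16 rose without WT replicate 2. The camera adjusted p of that list was 0.0046, 0.01 and 9.1e-06 without WT DMSO 1, WT DMSO 3 and WT C16 2. In the WT replicate 2 libraries the median of these genes lay −3.57 (DMSO), −4.12 (C16) and −3.28 (RE) from WT DMSO 1, against 1.69 and 1.84 in WT C16 replicates 1 and 3.

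In total 144 genes rose and 323 fell of 15046 tested by edgeR in WT cells under C16, 27 and 165 of them by at least 2-fold. Libraries did not overlap for 4497 genes (29.9%), against 10% by chance if the 6 libraries were exchangeable. WT replicate 2 stood apart in each group, so the chance share was lower here, by an amount that was not measured. The count of 467 was 0, 253, 2, 0, 1329 and 0 without WT DMSO 1, 2 and 3 and WT C16 1, 2 and 3 in turn, 3646 with replicate blocks, 1671 by DESeq2 and 6341 without WT replicate 2. It was 206 with no low-count filter, 81 with only the 6 libraries of the contrast and 2999 when all 18 libraries shared 1 fit. The excess of falls depends on the setting: 803 rose and 868 fell by DESeq2, 672 and 657 without WT C16 2, 1565 and 1434 when all 18 libraries shared 1 fit and 3168 and 3173 without WT replicate 2.

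**Figure D4:**
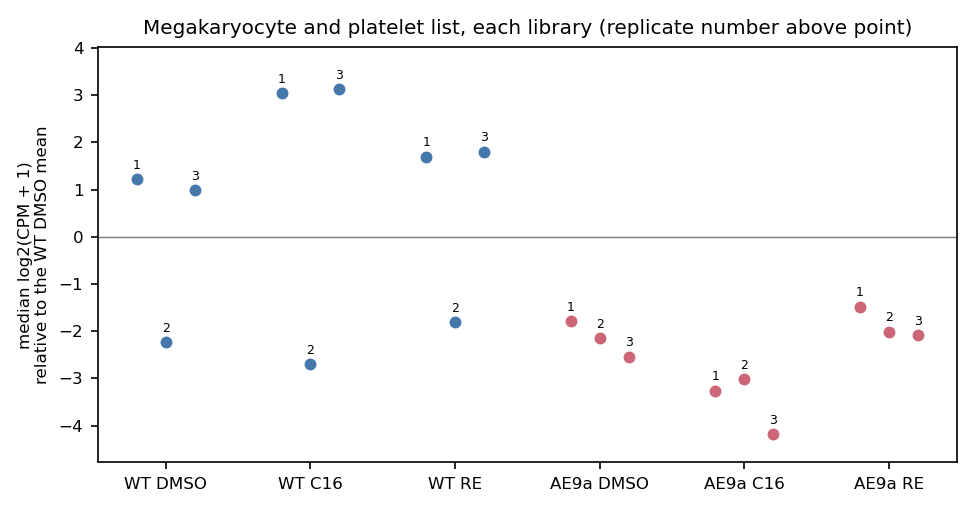
Median log2(CPM + 1) of the megakaryocyte and platelet list in each of the 18 libraries, relative to the mean of WT DMSO libraries, with points numbered by replicate. WT replicate 2 lies far below WT replicates 1 and 3 under each treatment, and AE9a libraries lie low throughout.

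RE lowered 4 genes in WT cells, a HOXA gene among them. Adgrl4 (chromosome 3, 151143519 to 151250718) fell by −3.54 ± 0.24 (adjusted p = 0.0068), from 16.8 ± 3.99 to 1.41 ± 0.367 CPM, Arhgap32 by −1.85 ± 0.14 (adjusted p = 0.0075), Tcf4 by −0.88 ± 0.07 (adjusted p = 0.011) and Hoxa6 (chromosome 6, 52181838 to 52185652) by −3.07 ± 0.29 (adjusted p = 0.022), from 1.89 to 0.214 CPM. Hoxa9 showed −2.51 ± 0.42 (0.702 against 4.11 CPM, adjusted p = 0.24, and 0.02 with replicate blocks), Hoxa7 −2.68 ± 0.39 (adjusted p = 0.24, and 0.037 with blocks) and Cd34 −0.90 ± 0.15 (adjusted p = 0.24, and 0.033 with blocks). Of 15 HOXA-MEIS1 genes, 1 fell (7 over the list alone, 5 with replicate blocks and 8 without WT replicate 2). The HOXA-MEIS1 median was −1.45 (camera adjusted p = 7.8e-22, and adjusted p = 0.0015 with an estimated correlation). Of 28 HSC and stemness genes, 0 fell at the all-gene threshold, 5 over the list alone and 4 with replicate blocks. The stemness median was −0.19 (camera adjusted p = 1e-06, and adjusted p = 0.83 with an estimated correlation).

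By edgeR 0 genes rose and 4 fell of 15046 tested in WT cells under RE, and 665 had p under 0.05 before adjustment. Libraries did not overlap for 2041 genes (13.6%), against 10% by chance if the 6 libraries were exchangeable. As WT replicate 2 stood apart in each group, the chance share was lower, so 13.6% cannot be read as close to chance. Without WT DMSO 1, 2 and 3 and WT RE 1, 2 and 3 in turn, the count was 0, 1, 1, 0, 0 and 1, and the adjusted p of Adgrl4 was 0.051, 0.089 and 0.059 without WT DMSO 1, WT RE 1 and WT RE 2. Arhgap32, Tcf4 and Hoxa6 lost their calls in each of these fits, with adjusted p for Arhgap32 of 0.051, 0.05, 0.069, 0.089, 0.059 and 0.095, for Tcf4 of 0.14, 0.081, 0.13, 0.15, 0.068 and 0.12, and for Hoxa6 of 0.18, 0.14, 0.16, 0.24, 0.099 and 0.24. The count was 77 with replicate blocks, 71 by DESeq2, 3 by limma-voom, 0 with only the 6 libraries of the contrast, 29 when all 18 libraries shared 1 fit and 1219 without WT replicate 2.

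Compared directly in WT cells, C16 left higher levels than RE of 5 of 15 HOXA-MEIS1 and 22 of 25 ribosome biogenesis genes, and lower levels of 10 of 27 interferon and 7 of 15 B lineage genes. Adgrl4 was higher by 3.66 ± 0.24 (17.4 against 1.41 CPM, adjusted p = 0.0037), Hoxa6 by 3.13 ± 0.29 (adjusted p = 0.004), Hoxa5 (chromosome 6, 52178768 to 52181437) by 2.16 (adjusted p = 0.011) and Cd34 by 1.16 ± 0.15 (117.0 against 54 CPM). Hoxa9 was higher by 2.57 ± 0.42 (adjusted p = 0.014, and 0.059 without WT RE 1). Epx was lower by −3.88 ± 0.41 (8.4 against 127.6 CPM), Zbp1 by −2.10 ± 0.20, Cxcr2 by −1.46 ± 0.17 and Jup by −1.87 ± 0.21. Larger falls included Stfa2 (−5.34, adjusted p = 0.041) and Stfa2l1 (−4.27, adjusted p = 0.047). Both lost their calls without any single library of the contrast, and shrank to −2.84 and −2.12 without WT RE 2. Of 15 HOXA-MEIS1 genes, 5 were higher (7 over the list alone and 9 with replicate blocks). The HOXA-MEIS1 median was 1.46 (camera adjusted p = 4e-07, and adjusted p = 0.04 with an estimated correlation, or adjusted p = 0.2 with an estimated correlation and blocks). The HOXA-MEIS1 count was 3 without WT RE 1 and 10 without WT replicate 2.

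Of 25 ribosome biogenesis genes, 22 were higher in WT cells under C16 than under RE (25 over the list alone). The ribosome biogenesis median was 0.82 (camera adjusted p = 2.5e-18, and adjusted p = 0.42 with an estimated correlation). That count was 11, 12, 0, 6 and 7 without WT C16 1, WT C16 3, WT RE 1, WT RE 2 and WT RE 3 in turn. Of 27 interferon response genes, 10 were lower (16 over the list alone and 21 with replicate blocks). The interferon median was −1.19 (camera adjusted p = 1.5e-08, and adjusted p = 0.42 with an estimated correlation). The interferon count was 4, 3, 2 and 5 without WT C16 1, WT C16 3, WT RE 1 and WT RE 3 in turn and 23 without WT replicate 2. Of 15 B lineage genes, 7 were lower (9 over the list alone). The B lineage median was −2.08 (camera adjusted p = 2.3e-06, and adjusted p = 0.42 with an estimated correlation). The B lineage count was 4, 4 and 4 without WT C16 1, WT C16 3 and WT RE 1. By edgeR 812 genes were higher and 977 lower of 15046 tested, 96 and 498 by at least 2-fold. Libraries did not overlap for 5250 genes (34.9%), against 10% by chance for exchangeable libraries, a share that was lower here because WT replicate 2 stood apart. The count of 1789 was 563, 522, 302, 780 and 590 without WT C16 1, WT C16 3, WT RE 1, WT RE 2 and WT RE 3, 5145 with replicate blocks, 3003 by DESeq2 and 6737 without WT replicate 2. It was 920 with no low-count filter, 281 with only the 6 libraries of the contrast and 4497 when all 18 libraries shared 1 fit. The genes higher outnumbered those lower without WT C16 2 (1100 and 1061), without WT replicate 2 (3478 and 3259) and at a mean of at least 5 CPM (1112 and 833).

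The response to C16 differed between the genotypes in 13 of 22 erythroid genes, Kit and Runx1 among others. The log2 change in AE9a cells minus that in WT cells was −7.13 ± 0.72 for Car1 (adjusted p = 7.7e-05), −3.38 for Klf1, −3.23 for Hdc, −2.05 ± 0.44 for Kit (adjusted p = 0.0083) and −1.27 ± 0.25 for Runx1 (adjusted p = 0.0054). Clca3a1 stood at 59.6 CPM in DMSO and 1.21 CPM in C16 libraries of AE9a cells, and at 5.23 ± 4.21 and 67.6 ± 58.2 CPM in those of WT cells, a difference of −9.23 ± 1.91 (adjusted p = 0.007). Its level was 98.8, 0.439 and 103.7 CPM in WT C16 replicates 1, 2 and 3. Adgre1, a macrophage receptor gene, differed by 1.74 ± 0.30 and Arhgef37 by 3.88 ± 0.75. Levels of Car1 and Runx1t1 were low in WT DMSO cells, as given above, so a fall there could hardly be seen. The difference for Runx1 may include fragments of the fusion transcript, which only AE9a cells carry. Runx1t1 differed by −4.22 ± 1.75 (adjusted p = 0.12), Hoxa9 by 0.91 (adjusted p = 0.14, and 0.0055 with replicate blocks, 0.0014 without WT C16 2) and Wdr5 by 0.47 ± 0.16 (adjusted p = 0.063, and 0.0018 with blocks, 0.00096 without WT C16 2).

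Of 22 erythroid genes, 13 differed downwards in AE9a cells (14 over the list alone). Only 19 of the 22, and 18 of 22 mast cell, basophil and eosinophil genes, passed the count filter in the fit of WT libraries. For the rest a fall in WT cells could hardly be seen. The erythroid median was −3.37 (camera adjusted p = 2.6e-13, and adjusted p = 0.45 with an estimated correlation). Of 22 mast cell, basophil and eosinophil genes, 6 differed downwards (6 over the list alone and 10 with replicate blocks). The mast cell median was −2.32 (camera adjusted p = 0.00052, and adjusted p = 0.71 with an estimated correlation). The mast cell count was 3 without WT C16 1 and 3 without AE9a DMSO 2. Of 36 cell cycle genes, 1 differed upwards (0 over the list alone). The cell cycle median was 0.69 (camera adjusted p = 1.1e-06, and adjusted p = 0.78 with an estimated correlation). The cell cycle count was 35 with replicate blocks and 36 without WT C16 2. The 1 gene, Cenpf (adjusted p = 0.046), lost its call without any library of the contrast but WT DMSO 1 and WT C16 2 (0.065 to 0.13). Of 16 megakaryocyte genes, 2 differed downwards (0 over the list alone). The megakaryocyte median was −3.93 (camera adjusted p = 0.00029, and adjusted p = 0.78 with an estimated correlation). The megakaryocyte count was 16 with replicate blocks and 12 without WT C16 2. The 2 genes, Rab27b and Gp5 (adjusted p = 0.049 each), lost their calls without any library of the contrast but WT C16 2 (0.062 to 0.12). By edgeR 755 genes differed upwards and 1310 downwards in AE9a cells of 15809 tested, 250 and 852 by at least 2-fold. The count of 2065 was 1121, 6394, 1134, 1084 and 1366 without WT C16 1, WT C16 2, WT C16 3, AE9a DMSO 2 and AE9a C16 1, 5813 with replicate blocks and 8038 without WT replicate 2. The excess downwards turned with the setting: 3070 differed upwards and 2743 downwards with blocks, 3642 and 2752 without WT C16 2, and 4656 and 3382 without WT replicate 2.

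For RE, 0 of 15809 genes passed the edgeR test of a genotype difference, 676 having p under 0.05 before adjustment; DESeq2 gave 34, limma-voom 0 and replicate blocks 7. The HOXA-MEIS1 list had a median difference of 0.00 (camera adjusted p = 0.54). Erythroid genes had a median of −0.94, lower in AE9a cells (camera adjusted p = 4.3e-12, and adjusted p = 0.6 with an estimated correlation), and cell cycle genes −0.31 (camera adjusted p = 4.8e-08, and adjusted p = 0.86 with an estimated correlation), with 0.059 for cell cycle genes without WT RE 2. The edgeR count was 1 without WT DMSO 2, 1 without AE9a RE 1, 1 with only the libraries of the contrast and 201 without WT replicate 2.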

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

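Tests of the explanations below were chosen after the results had been seen. With 3 libraries per group, no library was tested by itself as far from its group.

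C16 drew different responses from 2065 genes in AE9a and WT cells. The largest differences upwards in AE9a cells were Arhgef37 (3.88), Fn1 (3.23), Snhg11 (2.94), Ifi209 (2.78) and Ms4a4c (2.77), and downwards Clca3a1 (−9.23), Bmp2 (−8.33), Ahsp (−8.19), Kcnj5 (−8.16) and Nudt11 (−7.99). Ahsp and Nudt11 had 3 and 0 fragments in WT DMSO libraries, so their sizes are uncertain. The call of Fn1 was lost without WT DMSO 2 (adjusted p = 0.063), WT C16 1 (0.062), WT C16 3 (0.06), AE9a DMSO 2 (0.065) and AE9a C16 3 (0.06), and that of Kcnj5 without any library of the contrast but WT DMSO 2 and WT C16 2 (0.054 to 0.09). By list the median differences were −3.37 for erythroid, −3.93 for megakaryocyte, −2.32 for mast cell, −0.58 for replication-dependent histone and −0.52 for p53 target genes, and 0.69 for cell cycle, 0.97 for monocyte, 1.5 for primary granule and 0.15 for cytosolic ribosomal protein genes. The camera call of each of these 9 lists was lost with an estimated correlation (adjusted p = 0.45 to 0.81). Without WT C16 2 the genes that passed numbered 11 (from 0) for primary granule, 10 (from 2) for monocyte, 39 (from 5) for ribosomal protein, 10 (from 1) for p53 and 8 (from 3) for histone genes, in the direction of the median, and with replicate blocks 11, 11, 13, 14 and 8. Cd68, 1 of the 2 monocyte genes (adjusted p = 0.04), lost its call without any library of the contrast but WT DMSO 2, WT C16 2 and AE9a DMSO 3 (0.061 to 0.11). The ribosomal protein count was 1 to 3 without any other library of the contrast. With replicate blocks the camera call was lost for histone (adjusted p = 0.059) and ribosomal protein genes (0.065). Without WT C16 1 it was lost for ribosomal protein genes (0.058), and for p53 targets without WT DMSO 2 (0.075), WT C16 1 (0.058) or WT C16 3 (0.058). For RE they were −0.94 for erythroid, −0.31 for cell cycle and −0.34 for monocyte genes, calls lost with an estimated correlation (adjusted p = 0.6, 0.86 and 0.86). The call was lost for cell cycle genes without WT RE 2 (0.059), and for monocyte genes without WT DMSO 3 (0.22), WT RE 2 (0.72), AE9a DMSO 3 (0.051) or AE9a RE 3 (0.38).

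Loss of Runx1t1, mast cell and erythroid transcripts in AE9a C16 libraries could come from mislabelled WT libraries. Over 522 genes lower in AE9a cells these libraries lay at 0.89, 0.91 and 0.98 on a scale of 0 for WT and 1 for AE9a, but WT C16 2 lay at 0.58, so this position does not exclude wrong labels. Over 645 genes higher in AE9a cells they lay at 0.00, 0.07 and −0.29, the WT level, and WT C16 2 lay at −0.29. Runx1t1 in AE9a C16 1 and 2 (2.35 and 4.06 CPM) lay above the 0.402 CPM of the highest WT library, and in AE9a C16 3 (0.205 CPM) it did not. Loss of 1 cell population that expresses neither list, with all other cells as before, would move neutrophil and granule markers alike. They differed by −2.57, which argues against that form only. Which of these genes the lost cells would express is not known, so loss of 1 population is not excluded. A mixture of cell loss and changed expression remains open as well.

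WT replicate 2 stood apart from WT replicates 1 and 3 in megakaryocyte genes, by a median of −4.57. Chi-square per gene between libraries of a group was 4.67, 5.1 and 5.99 for WT replicates 1 and 3 under DMSO, C16 and RE, and 76.16 or more for pairs with replicate 2. Lower depth is excluded by a ratio of 0.99 between mean totals, and a swap with an AE9a DMSO or RE library by at most 0.11 CPM of Runx1t1. A mislabelled AE9a C16 library is not excluded for WT C16 2. Over 1592 genes that part AE9a C16 from WT replicates 1 and 3, WT DMSO 2, C16 2 and RE 2 lay at 0.54, 0.81 and 0.40. The scale was 0 for WT and 1 for AE9a C16. By root mean square log2 difference WT DMSO 2 lay 0.71, 0.71 and 0.76 from AE9a C16 replicates 1, 2 and 3, and WT RE 2 lay 0.86, 0.86 and 0.97. Those replicates lay 0.15 to 0.49 from each other, which argues against such a label for WT DMSO 2 and RE 2. The deviations of WT replicate 2 correlated between treatments at 0.72 or more, which restates the pattern, so whether its cells differed lastingly stays open.

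The absence of genes with a genotype difference in the RE response could come from spread from WT replicate 2, as 201 genes passed without it.

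Splitting the 6 libraries of a contrast otherwise gave at most 0 calls in each of the 7 contrasts between groups. With 10 splits, of which only 1, the real one, reached its own count, a share under 0.05 cannot be shown. The other splits mixed libraries of the real groups, so any real difference widened the spread within them. Few calls were therefore likely from the outset, and their 0 calls are not a chance count. Of 80 splits drawn for the C16 genotype difference, 5 gave as many genes as the real one, itself included, the highest other 6799. Those above it regrouped WT libraries only. In all 7 splits, the real one included, kept the AE9a groups and with them the C16 response of AE9a cells. The others of these gave 896 to 6799 genes, and all remaining splits at most 2. The 5 of 80 is therefore not a chance rate. For RE the real count was 0, so each of the 80 splits drawn had to give as many (80 did, the highest other 904), and this says nothing about chance.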

How the results depend on the processing

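Leaving out WT replicate 2 and the random-effect fit were chosen after the results had been seen; other alternatives were planned. Gene counts moved by over 1.5-fold as follows. WT C16 against DMSO (467): DESeq2 1671, no filter 206, blocks 3646, only the contrast's libraries 81, all 18 libraries 2999, without WT replicate 2 6341, leaving out 1 library 0 to 1329. WT RE against DMSO (4): DESeq2 71, blocks 77, only the contrast's libraries 0, all 18 libraries 29, without WT replicate 2 1219, leaving out 1 library 0 to 1. WT C16 against RE (1789): DESeq2 3003, no filter 920, blocks 5145, only the contrast's libraries 281, all 18 libraries 4497, without WT replicate 2 6737, leaving out 1 library 302 to 2161. AE9a RE against DMSO (4261): all 18 libraries 500, leaving out 1 library 2351 to 3852. AE9a against WT under DMSO (4225): without WT replicate 2 8172. C16 genotype difference (2065): blocks 5813, without WT replicate 2 8038, leaving out 1 library 1084 to 6394. RE genotype difference (0): DESeq2 34, blocks 7, only the contrast's libraries 1, without WT replicate 2 201, leaving out 1 library 0 to 1. Of 78 list calls, 3 remained with an estimated correlation. Between the C16 and RE responses of AE9a cells the correlation was −0.54 by Spearman and −0.54 at a mean of at least 5 CPM. Between the C16 response and the genotype difference it was −0.23 by Spearman. Simulations without responses and without a genotype difference gave −0.45 there. For WT RE against DMSO the adjusted p of the maturing neutrophil list ran from 1.7e-05 to 0.29 as libraries were left out, and its direction turned downwards without WT RE 2 (0.0029). Of 1083 named gene results, 0 reversed and 433 were the same throughout. Under some alternative 271 weakened, 241 strengthened and 151 that did not pass changed sign.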

Other observations

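The observations below were chosen after the results had been seen. In AE9a cells under C16 dendritic cell genes moved as well: 11 of 14 fell and 2 rose (11 and 2 over the list alone), H2-Ab1 by −1.02 ± 0.10, with a list median of −0.89 (camera adjusted p = 0.078, and 0.008 without AE9a DMSO 1; adjusted p = 0.63 with an estimated correlation). Of 24 p53 target genes 11 fell and 3 rose (11 and 3 over the list alone), Bbc3 by −1.45, and of 21 integrated stress response genes 7 rose and 7 fell (8 and 7 over the list alone), Phgdh rising by 1.11 ± 0.06. Of 79 cytosolic ribosomal protein genes 25 rose and 17 fell (24 and 17 over the list alone), with a median of 0.05. Interferon response genes varied between AE9a C16 replicates, with medians of 2.26, 2.04 and −0.02 in replicates 1, 2 and 3; of 28 tested 2 fell and 0 rose (0 over the list alone), 6 rose and 9 fell with replicate blocks, and 4 rose without AE9a C16 3. Egr1 fell by −2.17 ± 0.24, from 49.6 to 10.7 CPM.

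In AE9a cells under RE, 10 of 28 HSC and stemness genes fell, 3 rose and 15 did not pass (11 and 3 over the list alone), with a median of −0.26 (camera adjusted p = 0.00097, and adjusted p = 0.63 with an estimated correlation), Cd27 falling by −1.45 ± 0.10; 0 rose without AE9a DMSO 1, 0 without AE9a DMSO 3, 0 without AE9a RE 2 and 0 without AE9a RE 3. Of 28 interferon response genes 0 rose and 0 fell, and 1 fell with replicate blocks.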
